A study of Glycine max with 9 samples.

How the data were processed

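Leaves of the soybean line PI96983, which carries the Rsv1 resistance gene, were sampled after mock inoculation or inoculation with the avirulent strain SMV-L or the virulent strain SMV-G7 of soybean mosaic virus. Messenger RNA, small RNA and the degradome (the cut ends of messenger RNAs) were sequenced on an Illumina MiSeq, with 1 library per treatment and assay and 9 libraries in all. Each library was a pool of 3 biological replicates of 5 plants. There are no replicate libraries, so no value has a replicate error and no difference between treatments was tested against one.

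Per the file headers, the messenger RNA and small RNA tables were made with Strand NGS version 2.1 with standard parameters and quantification on known annotation, DESeq normalization, a threshold of 1 and a baseline set to the median of all samples. The deposited values are log2 values, and the median of the 3 libraries is 0 for each of the 53927 genes and each of the 550 small RNA loci, so they hold differences between libraries and no absolute level. The headers call the values log2 of RPKM, but most genes above the threshold in 1 library alone share the same worth of 1 read in that library. No division by gene length is visible in those genes, and genes of unreadable level could not be checked. The genome build and aligner behind both tables are not given in the sources used here. The degradome table was made by the authors with the PAREsnip pipeline of the UEA small RNA workbench on Ensembl Glyma1 cDNA and miRNAs of miRBase version 21. Its deposited fields are the normalised weighted fragment abundance in RPM (scaled to the total number of fragments), the short read abundance as counts of small RNA reads, and other PAREsnip fields, namely fragment abundance, weighted fragment abundance, category, cleavage position, p-value and alignment score. No column of the degradome table names a library, so it was described as a whole and the planned degradome comparisons were not made. In it, 66 entries with a shifted field were realigned and 25 empty lines were left out.

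The worth of 1 read in each library was read from features at the authors' threshold in the other libraries, whose remaining value falls on steps of whole reads. Of such genes, 82.9% in mock, 84.8% in SMV-L and 82.1% in SMV-G7 fell on whole reads, and so did 100% of such small RNA loci. A value was called whole within a relative tolerance of 4e-05%. Where the 3 values of a feature matched whole numbers up to 100 reads (messenger RNA) or 2000 reads (small RNA), the lowest such numbers were taken as its reads; they are lower bounds, since a common multiple would fit as well. Of the genes not listed at 0, 11755 had a library at the threshold, 9090 were read as whole numbers and 13446 could not be read. A decoy test on those 13446 genes, with the lowest library moved by a random step, read 0 as lying at the threshold. Most messenger RNA read numbers beside a library at the threshold were even (81.6% in mock), as would follow if both mates of a pair were counted, which was not tested.

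A gene or miRNA precursor counted as higher or lower when its deposited log2 values differed by at least 1 and the larger library stood at 10 or more normalized reads; features whose level could not be read were kept. Within lists, GO terms and families a gene or precursor was measured when any of the 3 libraries stood at 10 or more. It counted as higher or lower by the size of its change alone. Of 4658 such calls over 61 groups, 4449 (95.5%) were also kept by the filter on the larger of the 2 compared libraries. Features of unreadable level always pass that filter, so this share does not show that the calls reach 10 normalized reads. The planned pseudocount of 1 was not added, because the values are logarithms. The 13 gene lists, the 4 miRNA lists, the comparisons, the rule for named genes and the main alternative settings were fixed before the data were examined. The gene lists were pathogenesis-related proteins, WRKY factors, phenylpropanoid and isoflavonoid enzymes, light-harvesting and photosystem proteins, heat shock proteins, cytosolic ribosomal proteins, translation initiation factors, RNA silencing proteins, disease resistance proteins, the jasmonate pathway, glutathione S-transferases and peroxidases, cell wall proteins, and seed and nodule proteins as markers of other tissue. The miRNA lists were miRNAs of resistance genes, of the silencing machinery, of development, and of nutrient and stress responses. Members were found by name or description, using the symbols of the reference annotation for 33254 of 34376 Entrez identifiers and the descriptions of the degradome table. A list's median was placed among 10000 random lists, as a description of these libraries. These were matched in 20 bins of level where the level could be read, and in 1 further bin for all features of unreadable level. That further bin held 13446 of the 19085 measured genes, so most genes were not matched on level.

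The named genes are the 10 largest rises and 10 largest falls per comparison among genes with a name or description, up to 2 members per gene list, and every eIF5A and argonaute 1 gene; no argonaute 1 gene was found. The named miRNAs are the 10 largest rises and falls and the most abundant member of each listed family. Gene Ontology (GO) terms and symbol families were not among the fixed lists: 488 terms with at least 10 measured genes were ranked in the same way after the data had been seen, and terms, their members, symbol families and further miRNAs were named from that ranking. For a fold bound a library at 0 was set to 3 counts per library, taken as 3 reads for small RNA and 6 reads for messenger RNA. This takes 2 mates of a pair as 1 count, and the 6 was chosen after the data had been seen. Each "at least" fold takes the reads of the other library as exact. It leaves out their counting error, so a bound near 1 may not exclude equal levels. Intervals of a ratio are 95% exact Clopper-Pearson intervals of 2 read numbers. They cover counting error only, since amplified reads are not independent molecules. For messenger RNA they were computed on reads divided by 2, and reads that are lower bounds widen them. Intervals of a median are 95% binomial intervals, taken from the ranked values of its genes or precursors. These treat members as independent, though members may vary together or share reads, and they include no error between replicates.

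An exact two-sided conditional binomial test with Benjamini-Hochberg adjustment (threshold 0.05) was run on features with whole reads. It compares those libraries, not the conditions. For messenger RNA the reads were divided by 2, a choice made after a first version of the test had been run on the real and on simulated data, because simulated unchanged genes passed it. The number of features that counting error alone would put past the size rule was computed from the same binomial distribution. Reads matched as the lowest whole numbers may already lack a common factor of 2, and the division by 2 then comes on top. Reads set too low raise the numbers expected from counting error, also in simulated unchanged genes. They lower the numbers that pass the test. Alternatives were no filter, a filter at 50, a pseudocount of 5, rescaling by the median ratio, and the counting test; doubled read numbers, distinct miRNA values counted once, genes of unreadable level alone and the test on undivided reads were added after the data had been seen.

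The procedure was tested on simulated data with 200 changed genes among 18258. These were modelled on genes whose reads could be read back. The 13446 genes of unreadable level were not simulated, so the shares below do not extend to them. Of simulated unchanged genes kept by the filter, 30.2% (SMV-L versus mock), 20.2% (SMV-G7 versus mock) and 24.6% (SMV-G7 versus SMV-L) were at least 2-fold apart. None of these unchanged genes passed the counting test on divided reads, while 181, 97 and 155 passed it on undivided reads. The simulated messenger RNA reads were made as pairs, so this outcome follows from that reading and does not test it. Of 8-fold changes the divided test found 25.0%, 20.7% and 8.70% in messenger RNA. Simulated reads were read back and divided in the same way, which can lower these shares. In small RNA, with 364 simulated precursors, the test found 80.0%, 92.3% and 88.9%. Calculations used Python version 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures used matplotlib 3.10.9.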

Results

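Leaves of PI96983 soybean were inoculated 10 days after germination and sampled 14 days later, from plants grown at 22 °C for 16 h of light and 18 °C for 8 h of dark. The labels name 3 treatments: a buffer mock, SMV-L, an avirulent strain, and SMV-G7, a virulent strain; the study's title places them in a lethal systemic hypersensitive response that depends on the resistance gene Rsv1. Total counts per library are not in the tables, so only a relative depth could be read, from the worth of 1 read in each library. It is the scaling factor of the normalization, which can differ from the ratio of total reads. Against the mock library, the messenger RNA depth was 0.741 times for SMV-L and 1.45 times for SMV-G7, and the small RNA depth was 1.29 times and 1.32 times. The messenger RNA table listed 53927 genes, of which 34291 differed from 0 in some library. All 2741 genes that carry a symbol of their own in that table were listed at 0, against 33.0% of the 51186 others, so genes listed at 0 are not read here as unexpressed. The small RNA table held 530 miRBase precursors, 412 of them not listed at 0, and 20 further loci. Precursors of a family share reads: 135 small RNA loci had the same 3 values as another. The digits after GLYMA in a gene identifier give its chromosome, and all read numbers are listed in the order mock, SMV-L, SMV-G7.

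The comparison of SMV-L with mock asks what the avirulent strain changes in resistant leaves. Cysteine-rich receptor-like kinases (CRK), cell surface proteins that respond to pathogens, rose together: 18 of the 21 measured were higher and 0 lower, with a median log2 change of 2.44, or 1.43 with 0 reads set to 6. Cell wall GO terms, named after their values had been seen, had higher medians as well. Of 20 genes for xyloglucan:xyloglucosyl transferases, which cut and rejoin wall polymers, 15 were higher and 1 lower (median 2.25, or 1.85 with 0 reads set to 6). Of 37 cellulose synthase genes 18 were higher and 3 lower (median 0.96). The defence marker PR1-6 (GLYMA15G06780), a pathogenesis-related protein, went from 0 reads in mock to 45 reads, at least 10.1-fold higher. Photosynthesis genes showed no such shift, with 5 of 120 higher, 19 lower and a median of -0.18.

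Of the 18265 genes kept in this comparison, 3361 were higher and 3310 lower with SMV-L. Among genes with a name, GASA9 (GLYMA06G04740), a gibberellin-regulated peptide, had 0 reads in mock and was at least 27.7-fold higher. A ribulose bisphosphate carboxylase small chain gene (GLYMA19G06390), the carbon-fixing enzyme of the chloroplast, rose by 7.21 on the log2 scale, and which of these 2 rises is the larger is not settled. Of the terpene synthases, which make volatile and defensive terpenoids, 3 were among the named rises: TPS21 (GLYMA17G05500) rose by 6.67, TPS5 (GLYMA07G30710) by 6.63, and TPS3 (GLYMA06G45780) from 0 to 50 reads, at least 11.2-fold. IOMT1 (GLYMA13G24210), an O-methyltransferase by its name, had 0, 71 and 17 reads and was at least 16.0-fold higher with SMV-L. An annexin gene (GLYMA08G14460) had 0, 29 and 26 reads and was at least 6.52-fold higher. The serine/threonine protein kinase gene GLYMA12G32460 rose by 5.77 and GASA7 (GLYMA05G01845) by 4.83.

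The falls among named genes were smaller and closer to the detection limit. The aldehyde dehydrogenase gene ALDH6B3 (GLYMA15G06400) fell by 4.35 on the log2 scale. The ammonium transporter AMT1.5 (GLYMA10G31130) had 15, 0 and 0 reads, at least 1.85-fold lower with SMV-L. ALDH18B3 (GLYMA03G12240) had 12, 0 and 29 reads, at least 1.48-fold lower. Both bounds take the mock reads as exact and leave out their counting error. The remaining named falls (PTS-L2, HGO1, ALDH3J1, NF-YC04, LHP1-1, BES1-11 and NF-YA13) went from between 10 and 13 reads in mock to 0 reads.

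Among the fixed lists, 5 of 62 WRKY transcription factors, regulators of defence genes, were measured and 52 were listed at 0; 3 rose and none fell, with a median of 2.29, at percentile 99.96 of 10000 matched random lists. WRKY27 (GLYMA15G00570) rose by 4.82 and the WRKY gene GLYMA09G41050 by 3.19. Of the pathogenesis-related list only PR1-6 was measured, at a log2 change of 5.93 or, with the mock library set to 6 reads, 3.34; without the filter on low values the list had 3 genes and a median of 1.44 at percentile 92.0. The 2 measured heat shock genes, both HSP90 chaperones, had a median of 1.95, which became 0.66 with 0 reads set to 6: HSP90A2 (GLYMA16G29750) had 0, 7 and 28 reads, and HSP90A1 (GLYMA09G24410) changed by 0.66. Of the light-harvesting list 3 genes were measured (median 1.43) and 2 rose, the carboxylase gene above and a photosystem II psb28 gene with 5, 10 and 11 reads. Of the 2 measured phenylalanine ammonia-lyase genes, the entry enzyme of phenylpropanoid synthesis, GLYMA20G32135 fell by 1.71 and GLYMA10G35381 changed by -0.89. The single measured lipoxygenase gene of the jasmonate list (GLYMA16G01070) rose by 1.14, and without the filter the list had 2 genes and a median of 0.50. None of the 12 ribosomal protein genes (median -0.36), the 2 initiation factors (median -0.06) and the 5 genes of the disease resistance list (median -0.53) passed the size rule; 4 of those 5 are TIR1 auxin receptors, found by their name. Of the glutathione list 5 glutathione peroxidases and 1 peroxisomal ascorbate peroxidase were measured (median -0.15); of these 6, 1 rose and 1 fell. The cell wall list matched 2 genes with 0 measured, the 3 matched seed and nodule genes were listed at 0 in every library, and the silencing list matched 0 genes.

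GO terms also cover genes that have no symbol. With SMV-L, defense response genes were higher in 47 of 111 cases and lower in 17 (median 0.69, percentile 100, or 0.44 with 0 reads set to 6), led by GLYMA16G24920 at 4.66. ADP binding, the term that nucleotide-binding resistance receptors carry, had 66 of 188 genes higher and 39 lower; its median of 0.40 became 0.28 with 0 reads set to 6 and 0.00 without the filter on low values. Polysaccharide binding, a term of wall-associated receptor kinases, had 18 of 25 genes higher and 0 lower, with a median of 2.36, or 1.29 with 0 reads set to 6 and 0.43 without that filter. Apoplast genes, whose products lie in the cell wall space, were higher in 18 of 31 cases and lower in 2 (median 1.79, or 1.28 with 0 reads set to 6). Of the 488 terms ranked, 39 lay above percentile 99.5 and 11 below percentile 0.5, where genes that vary independently would put 4.88 in both together. Genes of a term may vary together and terms share genes, so the excess alone does not show an effect of the strain.

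Counting error sets a limit on the counts. Of the 4680 genes with whole reads, 1168 were at least 2-fold higher and 1028 lower. At the lowest reads that match, counting error alone would give 538 and 586. The exact binomial test, which compares those libraries, not the conditions, was passed by 217 and 68. Reads matched this way can be lower bounds, so the expected numbers lean high and the numbers passing lean low.

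The comparison of SMV-G7 with mock asks what the virulent strain changes. The medians of chromatin and cell division terms rose and those of photosynthesis terms fell, while many of their genes stayed within 2-fold. Nucleosome genes, which encode histones, were higher in 32 of 59 cases and lower in 1 (median 1.03), and DNA replication genes in 40 of 81 and lower in 3 (median 0.98). Photosynthesis genes were lower in 62 of 120 cases and higher in 3 (median -1.0), and the light-harvesting subset in 19 of 29 with 0 higher (median -1.23). The study's named gene, EIF5A (GLYMA02G12520), a translation factor, rose 4.07-fold, a log2 change of 2.02.

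Of the 18458 genes kept, 3581 were higher and 3007 lower with SMV-G7. EIF5A lies on the reverse strand of chromosome 2, where the degradome table places a transcript of it between 10813189 and 10815333 of the Glyma1 assembly; its change with SMV-L was -0.15. The 3 other genes described as eIF5A (GLYMA04G32950, GLYMA06G21290 and GLYMA17G11130) were listed at 0 in every library. Malate synthase, the glyoxylate cycle enzyme (MS, GLYMA17G13730), stood first among named rises by the deposited values; it had 2 reads in mock and 0 in SMV-L, and its SMV-G7 value was not a whole number of reads, so no interval was computed. PR1-6 had 82 reads with SMV-G7, at least 9.44-fold above mock. WRKY27 rose by 5.47, DIR22 (GLYMA01G31750), named as a dirigent protein of lignan synthesis, was at least 6.07-fold higher, the carboxylase gene GLYMA19G06390 rose by 5.14 and TPS5 by 4.64. The receptor-like kinases CRK39 (GLYMA11G32520) and CRK60 (GLYMA18G45175) rose by 4.73 and 4.66, CRK41 (GLYMA11G32600) had 0, 8 and 34 reads and was at least 3.92-fold higher, and CRK13 (GLYMA09G27782) was at least 3.54-fold higher. Across the family 19 of 21 measured CRK genes were higher and 0 lower, with a median of 3.10, or 1.94 with 0 reads set to 6.

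The named falls included transporters and photosynthetic enzymes. The ammonium transporters AMT1.4 (GLYMA10G31110; 25, 59 and 0 reads) and AMT1.5 were at least 6.03-fold and at least 3.62-fold lower. The glyoxalase gene GLYI-2 (GLYMA01G37360; 23, 26 and 0 reads) was at least 5.55-fold lower. The carbonic anhydrase genes GLYMA05G08590 and GLYMA19G01050, enzymes that supply carbon dioxide and bicarbonate, fell by 4.09 and 3.84. The sugar transporter SWEET31 (GLYMA13G09140; 12, 2 and 0 reads) was at least 2.89-fold lower, and a disease resistance gene (GLYMA13G26000), at 14 reads in mock and 0 with SMV-G7, at least 3.38-fold lower. IQD33 (GLYMA09G35920; 32, 8 and 3 reads) had a ratio of mock to SMV-G7 of 15.4 with a counting interval of 2.72 to 104. LAX1 (GLYMA01G28310), an auxin influx carrier, and MYB145 (GLYMA12G07110), a transcription factor, fell by 3.29 and 3.01.

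In the fixed lists, 4 of the 5 measured WRKY genes rose and none fell, with a median of 3.47, or 3.18 with 0 reads set to 6, and GLYMA09G41050 rose by 4.32. Both HSP90 genes rose (median 2.99, or 1.69 with 0 reads set to 6): HSP90A1 by 1.69 and HSP90A2 by at least 3.23-fold. PR1-6, alone in its list, stood at 5.83, or 3.24 with mock set to 6 reads; without the filter the list of 3 genes had a median of 1.47 at percentile 87.9. Ribosomal proteins had a median of 0.59 at percentile 95.7, and 1 of 12 rose, the 60S protein L36 gene GLYMA20G29990 by 1.27. The initiation factors had a median of 0.63, made of EIF5A and an IF-2 gene (GLYMA08G18580) at -0.77. Phenylalanine ammonia-lyase gene GLYMA20G32135 fell by 2.22 while GLYMA10G35381 changed by 0.91 (median -0.65). The lipoxygenase gene rose by 1.09, and the jasmonate list without the filter had a median of 0.39. In the light-harvesting list (median 0.60) only the carboxylase gene rose, 1 of 6 genes of the glutathione list fell (median -0.22; the glutathione peroxidase GLYMA19G33650 by 1.36), and in the disease resistance list (median -0.71) only GLYMA13G26000 fell.

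By GO term, defense response genes were higher in 51 of 111 cases and lower in 12 (median 0.89), among them GLYMA16G24920 at 6.12 and GLYMA13G35320 with 0, 0 and 75 reads. ADP binding had 76 of 188 genes higher and 26 lower (median 0.56, or 0.55 with 0 reads set to 6). Polysaccharide binding had 19 of 25 higher and 2 lower, with a median of 2.54, or 1.82 with 0 reads set to 6 and 1.47 without the filter on low values. In the cell cycle term 13 of 33 genes were higher and 2 lower (median 0.89), with the B-type cyclins CYCB1;1 (GLYMA03G27910) and CYCB1;2 (GLYMA19G30720), which drive entry into mitosis, up by 2.58 and 2.51. Light-harvesting genes GLYMA18G03220 and GLYMA11G35130 fell by 4.88 and 3.47. The carboxylase gene GLYMA19G06390 moved the other way from the photosynthesis term. Of the 488 terms, 42 lay above percentile 99.5 and 18 below 0.5.

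Of the 4735 genes with whole reads, 1145 were at least 2-fold higher and 854 lower. Counting error alone would give 456 and 354 at the lowest reads that match, which lean high. The binomial test between libraries was passed by 250 and 225, which lean low.

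**Figure D1:**
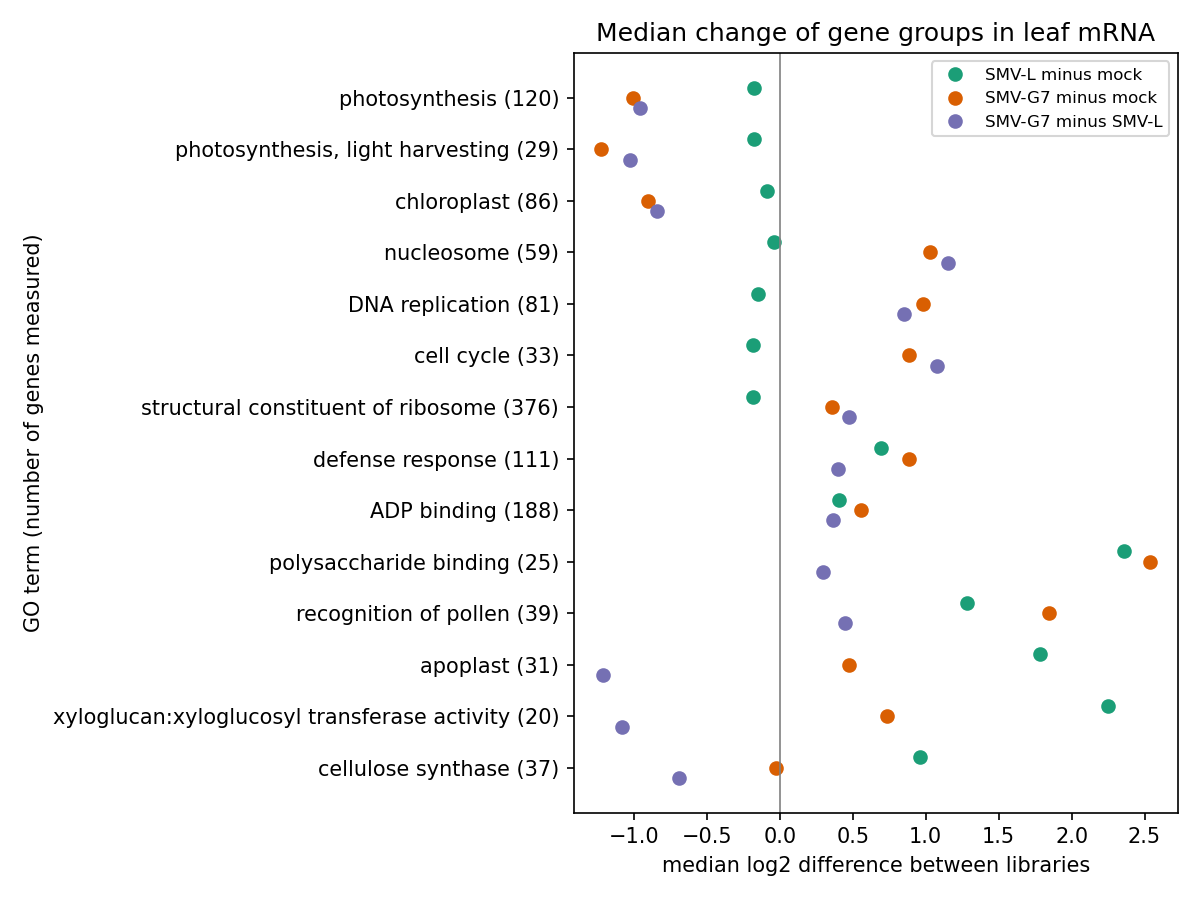
Each point is the median log2 difference (horizontal axis) of the measured genes of a GO term (vertical axis, number of genes in brackets) between 2 messenger RNA libraries, coloured by comparison. Photosynthesis lies at -1.0 and nucleosome at 1.03 for SMV-G7 minus mock, while both lie near 0 (-0.18 and -0.04) for SMV-L minus mock; the terms were picked after their values had been seen.

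The comparison of SMV-G7 with SMV-L asks how the virulent and the avirulent strain differ in the same resistant line. With SMV-G7, the medians of histone and DNA replication genes were higher and those of photosynthesis, apoplast and xyloglucosyl transferase genes lower. Many members of these terms stayed within 2-fold. Nucleosome genes were higher in 33 of 59 cases and lower in 1 (median 1.15), DNA replication genes in 34 of 81 with 0 lower (median 0.85, or 0.74 with 0 reads set to 6), and photosynthesis genes were lower in 55 of 120 and higher in 6 (median -0.96). Apoplast genes were lower in 16 of 31 cases and higher in 5 (median -1.21), and xyloglucosyl transferases in 10 of 20 with 3 higher (median -1.08); without the filter on low values the latter median, over 37 genes, was -0.0019. EIF5A was 4.52-fold higher with SMV-G7 than with SMV-L, a log2 change of 2.18.

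Of the 18357 genes kept, 3435 were higher and 2922 lower with SMV-G7. Malate synthase was at least 20.5-fold higher. Aldehyde dehydrogenases, which oxidise aldehydes and include the proline-forming ALDH18 type, supplied several of the named rises: ALDH18B1 (GLYMA01G24530) rose by 4.15, and ALDH18B3 and ALDH2C7 (GLYMA09G32160; 4, 0 and 22 reads) were at least 2.47-fold and at least 1.88-fold higher. FWL4 (GLYMA05G34876; 6, 0 and 24 reads) was at least 2.05-fold higher, GRF8 (GLYMA09G34565; 6, 0 and 20 reads), a growth-regulating factor, at least 1.71-fold, and IQD10 (GLYMA04G05520) at least 1.57-fold. The kinase gene S6K1A (GLYMA09G41010), whose product phosphorylates a ribosomal protein, rose by 3.73. ALDH3H1 (GLYMA04G42740) had 12, 1 and 20 reads, a ratio of SMV-G7 to SMV-L of 10.2 with a counting interval of 0.728 to 222. PUB8 (GLYMA02G35350), named as a U-box ubiquitin ligase, had 0 reads in mock and 1 read with SMV-L.

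AMT1.4 was at least 19.2-fold lower and GLYI-2 at least 8.46-fold lower with SMV-G7 than with SMV-L, and AMT1.3 (GLYMA10G31080) fell by 3.59. The terpene synthase TPS3 was 24.4-fold lower, with a counting interval of 6.09 to 213, and TPS21 fell by 4.25. The peptides GASA9 and GASA1 (GLYMA02G41280) fell by 4.59 and 4.25. The carbonic anhydrase genes GLYMA05G08590 and GLYMA19G01050 fell by 4.30 and 3.68, and the kinase gene GLYMA12G32460 by 3.33. PR1-6 differed by -0.10, a ratio of 1.07 with a counting interval of 0.628 to 1.87.

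In the lists, 2 of 5 WRKY genes were higher (median 0.89, or 0.65 with 0 reads set to 6), among them GLYMA09G41050 by 1.13, and both HSP90 genes were higher by 1.04 and 1.03. For HSP90A2 the counting interval of its ratio was 0.563 to 7.48. Of 12 ribosomal protein genes 2 were higher and 0 lower (median 0.62, percentile 96.0), and of the 2 phenylalanine ammonia-lyase genes GLYMA10G35381 rose by 1.80 (median 0.64). The initiation factor list had a median of 0.69, the light-harvesting list -0.83 with 1 gene lower, the jasmonate list -0.05 (-0.11 without the filter), the disease resistance list -0.16 with 1 gene lower and the glutathione list -0.32 with 1 higher and 1 lower. By GO term, structural genes of the ribosome were higher in 87 of 376 cases and lower in 13 (median 0.47, or 0.46 with 0 reads set to 6), and defense response genes in 37 of 111 and lower in 9 (median 0.40). Of the 488 terms, 34 lay above percentile 99.5 and 39 below 0.5.

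Of the 4660 genes with whole reads, 1011 were at least 2-fold higher and 908 lower. Counting error alone would give 566 and 303 at the lowest reads that match, which lean high. The binomial test between libraries was passed by 57 and 178, which lean low.

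Many genes moved the same way with both strains. Among the 17638 genes kept in both comparisons with mock, 1723 were higher with both strains and 1302 lower with both, while 94 were lower with SMV-L and higher with SMV-G7, and 77 the reverse. Both comparisons share the mock library, so chance alone makes them alike, and unchanged genes were simulated with 1 mock library for both. That simulation carries counting error only. A mock library that deviates for another reason would move both comparisons alike, which cannot be told apart from a change shared by the strains. Among the 4023 genes with whole reads in all 3 libraries, 430 were higher and 442 lower with both, where the simulated genes gave 200 and 80.6. In opposite directions, 13 were lower with SMV-L and higher with SMV-G7 and 18 the reverse, where they gave 14.2 and 5.66.

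Small RNAs were compared with SMV-L first. MiRNAs of nutrient and stress responses fell as a group: all 22 measured precursors of that list, with 16 distinct values, were lower, with a median of -2.57, or -2.30 with 0 reads set to 3 and -1.75 with a pseudocount of 5. They include miR397 and miR408, which act on copper enzymes such as laccases, miR398, which acts on superoxide dismutase, and miR395 and miR399 of sulfate and phosphate supply. MIR397a had 143, 21 and 798 reads and fell by 3.13, MIR398c by 3.28, and MIR408b had 385, 108 and 913 reads and fell by 2.20. The development family miR171 rose instead, with 10 of its 12 distinct values higher and 0 lower; MIR171q had 27, 179 and 67 reads and rose by 2.36.

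Of 220 miRNA precursors kept, 38 were higher and 65 lower with SMV-L. MIR319f had 26, 0 and 10 reads and was at least 11.2-fold lower, MIR169b had 18, 0 and 6 reads and was at least 7.72-fold lower, and MIR395l had 13, 0 and 0 reads and was at least 5.58-fold lower. The other MIR395 precursors measured (h, i, j and m) had 11 or 12 reads in mock and 0 with either strain. MIR5371 had 774, 99 and 256 reads and fell by 3.33, and MIR171c rose by 2.17. Named rises at low reads were MIR4353 with 14 reads against 1 in mock (ratio interval 1.65 to 460) and MIR4360 with 27 against 2 (2.64 to 91.0). Of the 104 measured development precursors 22 were higher and 28 lower, with a median of -0.15 that became 0.014 on rescaling. MiRNAs that target resistance genes (12 measured, median 0.20, or 0.37 rescaled) and the silencing machinery (9 measured, median 0.30) had 0 members past the size rule. Among tested precursors 28 were higher and 45 lower by the binomial test between libraries, where counting error alone would put 4.93 and 4.01 past the size rule. Rescaling by the median ratio moved every small RNA change by 0.17 for SMV-L versus mock, 0.055 for SMV-G7 versus mock and -0.11 for SMV-G7 versus SMV-L.

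With SMV-G7 against mock, a few soybean miRNAs rose by a wide margin. MIR4416c rose by 8.10 on the log2 scale and MIR5786 by 7.15. MIR5761a had 5, 2 and 382 reads and rose by 5.85, and MIR5761b had 2, 0 and 216 reads, a ratio with a counting interval of 22.4 to 679. MiR390, which starts trans-acting small RNA production, rose in all 6 of its distinct values (median 1.56), and MIR390f had 170, 492 and 663 reads. With SMV-L against mock 5 of these 6 values were higher and 0 lower (median 1.06). The miR169 family, which acts on NF-YA transcription factors, fell in 8 of 9 distinct values with 0 higher (median -2.62). MIR169o and MIR169r, which share a value, changed by -1.01, or -0.96 on rescaling. MIR169n had 231, 63 and 8 reads, a fall of 5.25. With SMV-L against mock the family was lower in 5 of 9 distinct values and higher in 1 (median -1.50).

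Of 223 precursors kept, 47 were higher and 54 lower with SMV-G7; on rescaling 50 were higher and 40 lower, so which direction prevails depends on the scaling. MIR390b and MIR390d had 0, 0 and 26 reads each and were at least 6.56-fold higher, and MIR5225 had 0, 0 and 24 reads, at least 6.05-fold higher. MIR397a and MIR397b rose by 2.08 and 2.01. MIR5778 and MIR5559 went from 21 and 20 reads in mock to 0, at least 9.25-fold and at least 8.81-fold lower. MIR395l was at least 5.73-fold lower and MIR164c (10, 2 and 0 reads) at least 4.41-fold lower. In the nutrient and stress list 15 of 22 precursors were lower, or 11 on rescaling, and 2 higher (median -1.06, percentile 0.445). Development precursors were higher in 21 of 104 cases and lower in 30, or 21 on rescaling (median -0.18); within miR393, which acts on auxin receptors, MIR393a had 11, 16 and 66 reads and rose by 2.18 while MIR393h fell by 1.32. Among miRNAs of resistance genes 2 of 12 were higher and 0 lower (median 0.34): MIR1507c with 100, 176 and 315 reads rose by 1.25, and MIR2118b by 1.0, and on rescaling MIR2118a passed as well (1.02). In the silencing list (median -0.21) 0 of 9 passed; MIR168a and MIR168b, which act on argonaute 1, changed by 0.997, and by 1.05 on rescaling, which takes both past the size rule. The 175 tested precursors held 39 higher and 46 lower by the binomial test, where counting error alone would put 4.70 and 3.54 past the size rule.

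**Figure D2:**
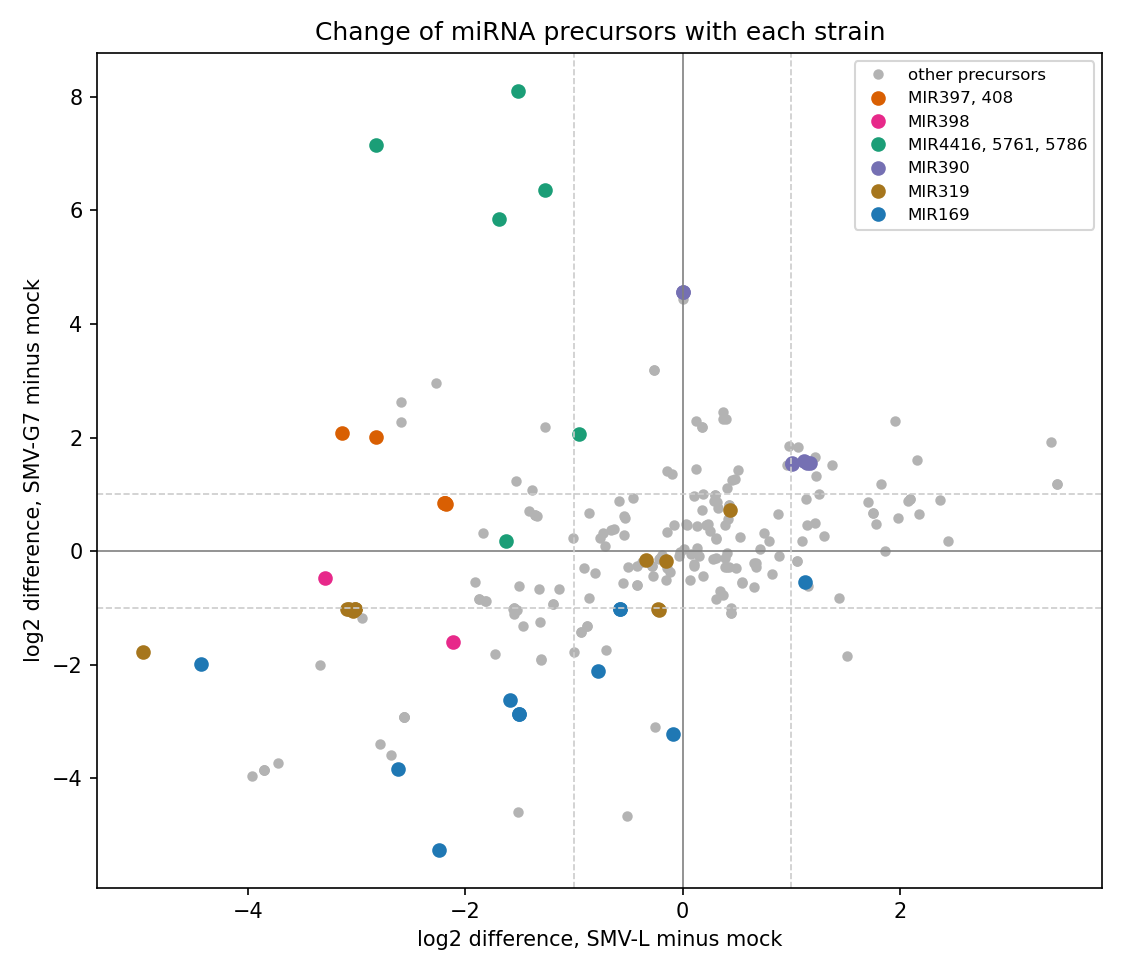
Each of the 238 points is a miRNA precursor, with its log2 difference between SMV-L and mock on the horizontal axis and between SMV-G7 and mock on the vertical axis; dashed lines mark the size rule and colours mark families. MIR4416c lies at -1.52 and 8.10, MIR397a at -3.13 and 2.08, and MIR169n at -2.24 and -5.25.

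Between the strains, miR397 and miR408 had the largest median rises among the families of the fixed lists, 5.02 and 3.03. MIR397a rose by 5.21 and MIR397b by 4.83 with SMV-G7 against SMV-L, and all 4 MIR408 precursors rose, MIR408b by 3.04. MIR5786 and MIR4416c rose by 9.98 and 9.62, and MIR5761b was at least 70.1-fold higher. The miR171 family was lower in 8 of 12 distinct values with 0 higher, and miR169 lower in 7 of 9 with 1 higher.

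Of 218 precursors kept, 56 were higher and 37 lower with SMV-G7. MIR156g (5, 0 and 41 reads) and MIR1535a (4, 0 and 41 reads) were each at least 13.3-fold higher, and MIR5037c (5, 0 and 32 reads) at least 10.4-fold higher. MIR5778 was at least 6.5-fold lower and MIR172h (3, 11 and 0 reads) at least 3.76-fold lower, and MIR169n fell by 3.02. In the nutrient and stress list 7 of 22 were higher and 0 lower (median 0.51, percentile 99.0). Development precursors were higher in 27 of 104 cases and lower in 24, with a median of 0.023; on rescaling 22 were higher and 25 lower, with a median of -0.090. Of the silencing list 2 of 9 were higher (median -0.17), both MIR1515, and on rescaling 2 were also lower, MIR162a at -1.07 and MIR162c at -1.0. Of the resistance gene list 1 of 12 was higher, MIR2109 (median 0.081, or -0.033 rescaled), by 1.54. The 170 tested precursors held 40 higher and 29 lower by the binomial test, where counting error alone would put 2.93 and 2.95 past the size rule. Among the 205 precursors kept in both comparisons with mock, 12 were higher and 37 lower with both strains. Of those with whole reads 12 and 36 were, where unchanged precursors simulated with counting error only gave 2.12 and 0.74. A mock library that deviates for another reason would give such an excess too.

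The degradome table asks which messenger RNAs were cut at sites that pair with small RNAs, and it cannot be split by treatment. EIF5A had a site at position 125 of its transcripts, of category 2 on one and 3 on another, with 2 fragments, paired with the 22 nt small RNA CTTGGACTGAAGGGGAGCTCCT, which had 5 reads; the authors' p-values were 0.02 and 0.03. The 3 other eIF5A genes had sites as well: category 1 sites with 2 fragments and an authors' p-value of 0 at position 589 of GLYMA04G32950 and position 737 of GLYMA06G21290, and in GLYMA17G11130 a category 4 site. Of the known families, miR396 had sites of categories 0 to 2 in 9 genes, several of them growth-regulating factors such as GRF10 (GLYMA11G01060) and GRF22 (GLYMA14G10090). MiR169 had such sites in 5 genes, among them NF-YA09 (GLYMA09G07960) and NF-YA12 (GLYMA13G16770). MiR156 had them in 3 genes, and miR159, miR160, miR167 and miR172 in 2 genes each. MiR408 had a site in 1 gene, of category 4.

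The table held 16435 entries in 5162 genes for 6093 small RNA sequences. By category from 0 to 4 there were 420, 1174, 2803, 1517 and 10521 entries, so 64.0% lay in category 4, where no site had more than 1 fragment. No site in the table had more than 2 fragments, and the normalised values imply a total of 1649024 fragments. With at most 2 fragments per site the table cannot rank sites by their strength, and what sets that limit was not tested.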

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

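Of the tests in this part, the draws of apoplast genes and the test of background small RNA were set before their result was seen, and the other tests were chosen after it. The differences between the strains were not tested, since each strain has 1 library per assay.

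Some features moved in opposite directions with the 2 strains against mock. In messenger RNA 94 genes were lower with SMV-L and higher with SMV-G7, and 77 genes were higher with SMV-L and lower with SMV-G7. Of the 4023 genes with whole reads 13 and 18 did so, where simulated unchanged genes gave 14.2 and 5.66. Among these genes the first count shows no excess, though simulated numbers lean high where reads are lower bounds. Genes without whole reads in all 3 libraries were not simulated, so this gives no verdict on the 94 and 77 as a whole. In small RNA 6 precursors were lower with SMV-L and higher with SMV-G7: MIR3522, MIR397a, MIR397b, MIR4416c, MIR5041 and MIR5786. MIR5041 had 9, 4 and 28 reads, and its fall with SMV-L had an adjusted p of 0.133 in the binomial test between libraries.

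The medians of the laccases, copper enzymes of lignin formation, had opposite signs: over the 6 laccase genes measured, of 49 in the table, the median log2 change was 1.25 with SMV-L and -1.17 with SMV-G7. There were 3 higher and 1 lower in the first case and 0 higher and 3 lower in the second. Of the 3 lower with SMV-G7, 1 (GLYMA18G07240, whose level could not be read) was kept by the filter of 10 normalized reads in that comparison. In the order mock, SMV-L, SMV-G7, GLYMA01G27710 had 8, 19 and 4 reads, GLYMA03G14450 had 6, 27 and 2, and GLYMA14G06760 had 0, 24 and 2, so their direction with SMV-G7 rests on few reads. GLYMA18G07240 changed by 0.82 and -2.12, while GLYMA01G37930 (-1.07 and -0.81) and GLYMA18G06450 (-0.25 and -0.23) kept 1 sign. For the 4 genes with readable reads the raw reads went the same way. SMV-G7, the deeper library, held 22 raw reads of them against 76 in SMV-L, a ratio of 0.289 with an upper 95% bound of 0.562. The laccases were named because their scaled medians differ, so this followed from that choice and cannot decide on library depth as a cause. A shift of apoplast genes in general stays open and cannot be told apart: draws of 6 of the 25 other apoplast genes had a median change from SMV-L to SMV-G7 at or below that of the laccases (-3.08) in 1.13% of cases, but the laccases were named because their medians differ, so draws of genes not picked that way exclude nothing. Release from miR397 and miR408 in SMV-L, where both families were lower, stays open and cannot be told apart from other causes: the degradome table held 0 sites of these miRNAs in laccase genes, but only 2 in all genes and none above 2 fragments. A difference in the response to the strains also stays open, as untested.

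MIR4416c, MIR5761a, MIR5761b and MIR5786 were far higher with SMV-G7 than in the other small RNA libraries, while MIR4416a rose by 2.06 against mock and MIR4416b changed by 0.18. Counting error is argued against for MIR5761a and MIR5761b, because the 95% bounds of their ratio of SMV-G7 to mock were 24.6 to 179 and 22.4 to 679. The reads of MIR4416c and MIR5786 could not be read, but at the fewest reads that the authors' threshold allows the lower bounds were 74.5 and 64.0, so counting error is argued against there too. A broad rise of background small RNA in the SMV-G7 library is argued against as the source of these values. On the same scale, the 128 precursors outside these families with at most 100 reads in mock had a median change of 0.24 (95% interval -0.080 to 0.58). A rise shared by most precursors would be removed by the authors' scaling and could not be seen here. The virus strain and the library cannot be told apart, since SMV-G7 has 1 small RNA library.

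The small RNA table also lists 20 loci without a miRBase accession, which the comparisons leave out and of which 17 could be read as whole reads. With at least 10 reads in the infected library, 8 of these were at least 2-fold higher with SMV-L than with mock and 0 with SMV-G7. With fewer reads, 3 of the same loci also rose with SMV-G7: NEWGENE3 by 2.18 (6 reads), NEWGENE19 by 1.60 (8 reads) and NEWGENE2 by 1.01 (8 reads). NEWGENE13 fell by 1.21 with SMV-L. Their log2 changes with SMV-L were 2.57 (NEWGENE2), 3.54 (NEWGENE3), 1.39 (NEWGENE7), 1.68 (NEWGENE8), 1.51 (NEWGENE11), 1.27 (NEWGENE18), 2.34 (NEWGENE19) and 1.01 (NEWGENE20).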

How the results depend on the processing

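Doubled read numbers, distinct miRNA values, genes of unreadable level, the undivided counting test and all alternatives for GO terms were tests chosen after the results were seen. Rescaling by the median ratio left the 6 messenger RNA and 6 small RNA counts within 1.5 times, as did doubled read numbers (messenger RNA), and a pseudocount of 5 and distinct values counted once (small RNA). On rescaling 108 of 108 named gene values and 199 named miRNA values kept their side of the size rule, and 6 miRNA values did not. In messenger RNA it moved every log2 change by only 0.017 (SMV-L versus mock), -0.0029 (SMV-G7 versus mock) and -0.020 (SMV-G7 versus SMV-L). The deposited values were already scaled by DESeq, so the messenger RNA results could hardly change. For SMV-G7 versus mock, rescaling changed which direction had more precursors, from 47 higher and 54 lower to 50 and 40. Counts are given for SMV-L versus mock, SMV-G7 versus mock and SMV-G7 versus SMV-L in that order, because the filter and the test set how many features can count. Without the filter, messenger RNA had 7205, 7397 and 7595 genes higher and 8089, 6461 and 5538 lower; in small RNA 67 and 77 precursors were higher against mock, and 68 lower between the strains. With the filter at 50, 2379 genes were higher with SMV-G7 versus mock. In small RNA that filter left 14 higher and 42 lower with SMV-L, 24 and 25 with SMV-G7, and 15 lower between the strains. The exact binomial test gave 217, 250 and 57 genes higher and 68, 225 and 178 lower. On undivided reads it gave 786, 842 and 539 higher and 501, 594 and 575 lower. There simulated unchanged genes also passed, in a simulation that made reads as pairs. The median of the oxylipin biosynthesis term for SMV-G7 versus SMV-L, -0.58, became 0.0054 with the filter at 50 and with genes of unreadable level alone; the cause was not tested. Of the other GO medians 14 left the interval of their main value and 362 did not; of the list medians 14 did and 124 did not. No paired analysis was possible because each treatment has 1 library per assay. The degradome comparisons, their list medians and the comparison of messenger RNA with degradome changes were not run, because no degradome value is tied to a library, nor was a pseudocount of 5 for messenger RNA, whose level is unreadable for 13446 genes. Depth limits the low end. At the lowest reads that match, counting error alone would put 538 of 4680 genes with whole reads past the rule as higher with SMV-L.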

Other observations

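The tests in this part were all chosen after the result was seen. Values of further groups, named after they had been seen, follow. Microtubule motor genes, which encode kinesins and related motors, were higher in 29 of 104 cases and lower in 9 with SMV-G7 against mock (median 0.50), and GLYMA13G19580 had 2, 17 and 48 reads in mock, SMV-L and SMV-G7. Nucleolus genes were higher in 15 of 28 cases and lower in 1 with SMV-G7 against mock (median 1.03), against 4 higher and 2 lower with SMV-L. Triglyceride lipase genes were higher in 15 of 29 cases and lower in 4 with SMV-L (median 1.18), and higher in 14 and lower in 4 with SMV-G7 (median 0.95, or 0.82 with 0 reads set to 6). Isoprenoid synthesis genes were higher in 10 of 28 cases and lower in 1 with SMV-L (median 0.78). Of the 27 measured aldehyde dehydrogenase genes 11 were higher and 3 lower with SMV-G7 against SMV-L, with a median of 0.83, or 0.62 with 0 reads set to 6. Of 18 measured genes of the PHR family 5 were lower and 1 higher with SMV-G7 against mock (median -0.60, percentile 1.91). Among miRNAs, MIR319a had 163, 26 and 106 reads, and the 2 MIR160 precursors were higher with SMV-G7 against mock (median 1.87).

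With SMV-G7, the median of the histone genes was higher and that of the photosynthesis genes lower than in mock. A deeper SMV-G7 library is argued against, since depth moves a scaled value only at the threshold and 0 of the 179 genes had a library there. The authors' scaling between libraries moves all genes alike, so the distance of 2.03 between the medians on the log2 scale does not depend on it. Where each median stands against 0 does. The 95% intervals were 0.86 to 1.13 and -1.16 to -0.93. Both terms were named for their medians, so intervals that lie apart followed from that choice and decide nothing. Younger leaf tissue in the SMV-G7 pool cannot be told apart from an effect of the strain: miR396, which builds up as leaves age, had a median of -0.62 over 9 precursors (95% interval -0.87 to -0.17), lower but short of the fall of 1 set for it. With SMV-L, where the nucleosome median was -0.04, miR396 fell further (median -1.51, 5 of 9 lower), so its fall does not track the histone genes and decides nothing here. A response to the strain stays open, as untested.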
